A study of Mus musculus with 3 samples.

How the data were processed

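RNA of 3 lines of mouse OP9 cells was measured on 1 array each: the parental OP9 line, OP9 cells with GFP, and OP9 cells with GFP and Delta-like 1. Per the labels' protocols, total RNA was extracted with a column kit, amplified to amino allyl RNA, coupled to Cy5 and fragmented by the array maker's (Toray) protocol, with 1 colour per array. The deposited values are linear probe intensity on each array, and the authors scaled them so that the median over the probes with a value is 20 on each array, as seen from the values themselves. The scanner, the background correction and the rule that left cells blank are not given in the sources used here. Of 23473 probes, 6.32% were blank on the OP9 array, 6.53% on the OP9-GFP array and 6.62% on the OP9-DL array. Blank probes were mostly dim: of 2225 probes blank on 1 or 2 arrays, the median of the highest intensity was 1.8, and 9 reached 20 on some array. The highest intensity of each array was shared by 7 (OP9), 7 (OP9-GFP) and 4 (OP9-DL) probes. These brightest values may be lower limits, and they were used as they stand.

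The deposited intensities were used without further normalization, since the medians are equal, and log2 was taken with no added constant. The 20775 probes with a value on all 3 arrays were measured, and the 15581 with a mean log2 value at or above the 25th percentile (2.62, an intensity of 6.13) were compared. Probes were named from the platform's gene table: 16631 probes had 1 gene symbol, and the other 6842, without a single symbol, were counted but not named. Symbols were updated through a mouse gene table of the assembly GRCm38.p6: 12619 were current, 3947 were renamed through a synonym and 65 were kept as on the array. No coordinates are given, because the array's genome build is not given in the sources used here, and the gene table served for names and for the order of genes along chromosomes.

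With 1 array per line, the only results are differences between arrays, and no test, error or p-value can be had. Their number, 3, limits the precision. A probe was counted as higher or lower at a difference of 2-fold or more, and a line was counted as standing apart where it was 2-fold or more above, or below, each of the other two. The comparisons were OP9-DL against OP9-GFP, OP9-GFP against OP9, and OP9-DL against OP9. Since they share arrays, correlations and overlaps are given beside 100 random reassignments of each probe's values to the arrays.

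Before the data were examined, 29 gene lists with 786 entries were fixed. They cover Notch ligands, receptors, targets and machinery, adhesion molecules, integrins, matrix and its proteases, stromal factors, chemokines, interferon, adipocyte, osteoblast, smooth muscle, TGF-beta, Wnt, cell cycle, p53, cholesterol, glycolysis, stress, immediate early, ribosomal, reference and Hox genes, and markers of mast, other blood, endothelial and epithelial cells. Of the blood cell markers Itgam and Itgb2 are also integrins on another list, and no mast cell marker is on another list. Genes with several probes took the mean of their log2 values. The median log2 difference of each list is given with its percentile among 10000 random lists of the same size matched on brightness in 20 bins, as a description of these arrays. Genes of one pathway vary together, which random lists leave out, so a percentile is no probability.

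Named genes followed a rule fixed beforehand: Dll1, the other Notch ligands and receptors and the listed Notch targets; the 10 highest and 10 lowest genes that set OP9-DL apart, ranked by the smaller of both differences; the 6 highest and 6 lowest for OP9-GFP and for OP9; and the 2 highest and 2 lowest members of each list in OP9-DL against OP9-GFP. Other genes are named where a count of 5 or fewer needed them, or where the closing observations say that they were chosen after their values were seen; Ptprc and Kit were also chosen afterwards.

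Alternatives fixed beforehand were quantile, median and lowess scaling (span 0.3), no limit on dim probes or one at the 50th percentile, a constant of 2.2 added before log2, blanks set to the array's lowest value, thresholds of 1.5-fold and 3-fold, and the brightest probe per gene. Counting only probes with a symbol was added after the data were seen. The procedure was tested on simulated arrays of 15581 probes in which OP9-DL was set apart: it counted 6% of probes set at 1.5-fold, 36% at 2-fold, 92% at 4-fold and 90% at 16-fold, and 0.117% of probes left unmoved. Of 20 unmoved lists 20 lay inside the middle 95%, and a list moved by 0.5 lay outside. The simulated noise was normal and independent between probes, with a spread taken from OP9-DL against OP9-GFP. It held no differences between cultures and no genes that vary together, so these rates do not carry over to the real arrays. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.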

Results

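Gene expression was measured on 3 one-colour oligonucleotide arrays, 1 for each of 3 lines of mouse OP9 cells. OP9 is a stromal line from newborn calvaria of mice with the Csf1op mutation, widely used as a feeder layer for blood cell development. The first line was OP9 itself, the second carried green fluorescent protein (OP9-GFP), and the last carried GFP together with the Notch ligand Delta-like 1 (OP9-DL). Each array gave a value for 21989 (OP9), 21941 (OP9-GFP) and 21920 (OP9-DL) of 23473 probes, and 15581 probes with a value on all 3 arrays were bright enough to be compared. Each line had 1 array, so no difference here has a replicate check, no test was run, and what Delta-like 1 does cannot be separated from what else differs between the cultures. All intensities are the authors' scaled values, in which the median probe of every array has the intensity 20.

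The first comparison set the cells with Delta-like 1 against the cells with GFP alone, the pair that differs by the ligand according to the labels. Dll1, which encodes Delta-like 1, had an intensity of 14.0 on the OP9 array, 20.5 on the OP9-GFP array and 333.3 on the OP9-DL array. It was thus 16.3-fold higher on the OP9-DL array than on the OP9-GFP array and 23.8-fold higher than on the OP9 array. Of the 15581 probes, 360 were at least 2-fold higher on the OP9-DL array than on the OP9-GFP array and 424 were at least 2-fold lower, 5.03% in all.

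Other genes stood higher on the OP9-DL array than on both other arrays. Tpsab1, a mast cell tryptase, had intensities of 20.6, 9.0 and 818.9 on the OP9, OP9-GFP and OP9-DL arrays, and Cd48, a surface protein of blood cells, had 2.1, 3.0 and 114.4. Pcsk2, a prohormone convertase, was 14.4-fold higher than on the OP9-GFP array and 22.4-fold higher than on the OP9 array. Tmem176a was 48.9-fold and 13.6-fold higher, and 1700024B05Rik 24.7-fold and 13.9-fold. Nlrp2 stood at 3.1, 3.0 and 46.6. Xmr stood at 7.2, 3.6 and 314.5 and Akr1c12 at 9.1, 4.9 and 189.4, but both belong to families of near-identical genes that a probe can mix, so these values are uncertain. One probe of Pdgfrl read 2.4, 2.8 and 40.4, while the other read 24.6, 35.2 and 21.3.

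Other genes stood lower on the OP9-DL array than on both other arrays. Cd9, a tetraspanin of the plasma membrane, had intensities of 1722 on the OP9 array, 963.3 on the OP9-GFP array and 9.3 on the OP9-DL array, 104-fold below OP9-GFP and 185-fold below OP9. Adgre5, the adhesion receptor CD97, stood at 210.5, 211.2 and 4.1, and Slco2a1, a prostaglandin transporter, at 431.9, 427.0 and 14.4. Cd1d1, which presents lipid antigens, stood at 49.2, 19.3 and 1.3. Eva1b was 43.9-fold lower than on the OP9-GFP array and 43.0-fold lower than on the OP9 array, and Ddit4l, an inhibitor of mTOR signalling, stood at 160.9, 98.2 and 8.2. Pxdc1 stood at 122.8, 233.6 and 2.9, Akip1 at 224.8, 87.8 and 1.7, Pxylp1 at 144.6, 148.2 and 4.3, and Arl16 at 23.6, 23.1 and 1.3. Readings below the brightness limit of 6.13 give a direction but no firm fold: with a constant of 2.2 added before log2, the difference of OP9-DL against OP9-GFP went from -5.69 to -4.53 for Akip1, from -3.89 to -2.62 for Cd1d1 and from 3.96 to 3.23 for Nlrp2.

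**Figure D1:**
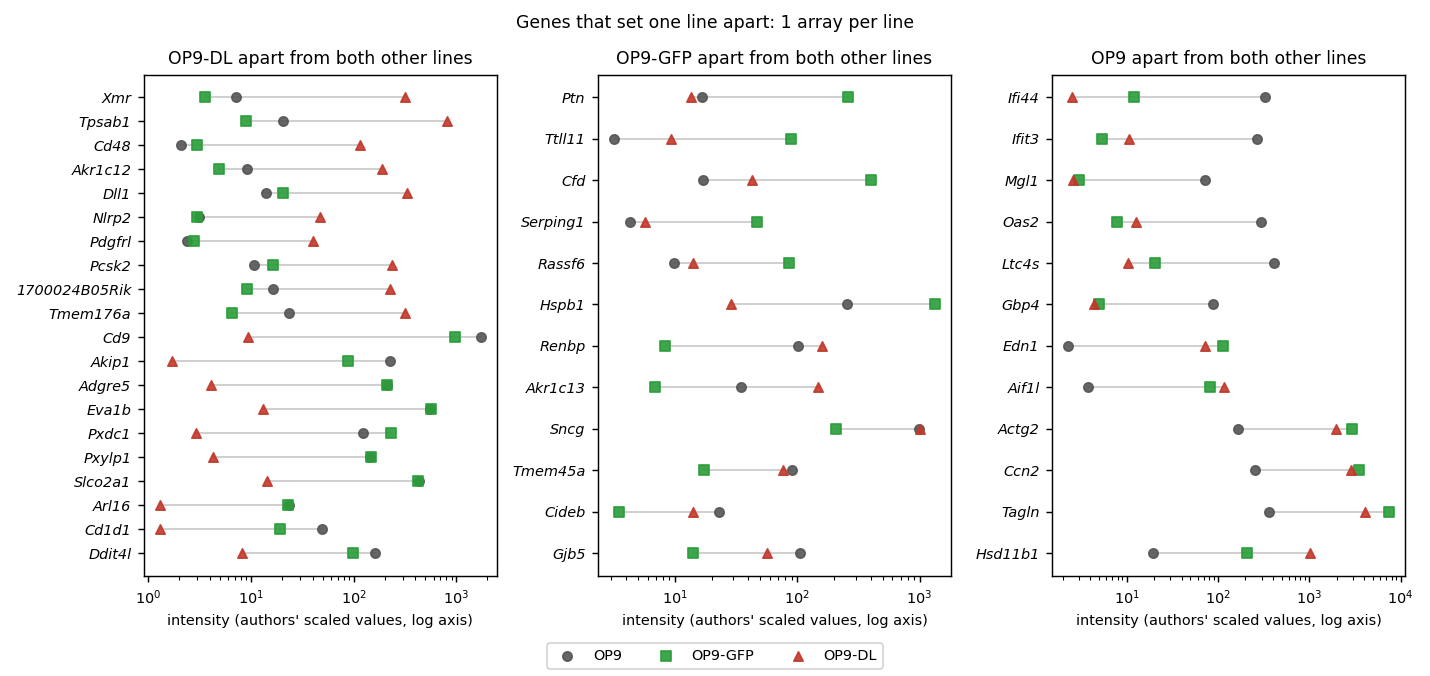
Intensity (authors' scaled values, log axis) of the genes that set one line apart from both others, 1 point per array: OP9 as grey circles, OP9-GFP as green squares, OP9-DL as red triangles. In the left panel Dll1 lies at 333.3 on the OP9-DL array against 14.0 and 20.5, and Cd9 at 9.3 against 1722 and 963.3; the other panels show the genes of OP9-GFP and of OP9.

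The other Notch ligands were mostly dim and close between the arrays. Of 8 ligands bright enough to compare, Dll1 and Dlk1 were at least 2-fold higher on the OP9-DL array than on the OP9-GFP array. Dlk1, a non-canonical ligand, had intensities of 8.1, 2.2 and 53.2 on the OP9, OP9-GFP and OP9-DL arrays. Dll4 (5.9, 7.2 and 7.9), Jag1 (9.7, 13.2 and 15.6) and Jag2 (6.1, 5.6 and 9.0) stayed within 2-fold, as did Dlk2 (67.3, 64.5 and 67.2) and Cntn1 (21.6, 16.5 and 19.0). Mfap5 stood at 16, 112.7 and 62.9. Mfap2 (5.3, 2.0 and 3.8) and Ccn3 (2.8, 3.5 and 4.7) were below the brightness limit, Dll3 had no value on any array, and Dner had 2.2 on the OP9 array, 2.0 on the OP9-DL array and none on the OP9-GFP array. Among the receptors, Notch1 had intensities of 22.1, 29.3 and 27.8 and Notch3 7.4, 7.2 and 4.9, while Notch2 (2.8, 2.6 and 2.4) and Notch4 (5.0, 5.3 and 3.7) were below the limit.

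None of the 17 comparable Notch target genes differed by 2-fold or more between the OP9-DL and OP9-GFP arrays. Hes1, the best-known direct target, had 55.9 on the OP9 array, 176.9 on the OP9-GFP array and 112.3 on the OP9-DL array. Hes5 stood at 80.1, 87.6 and 117.4, Hes7 at 15.1, 14.5 and 14.6, and Hey1 at 9.2, 11.5 and 7.5. Dtx4 (22.9, 30.4 and 52.2) and Il2ra (14.0, 10.3 and 15.6) had the highest differences of OP9-DL against OP9-GFP, 0.78 and 0.60 on the log2 scale, and Efnb2 (15, 68.8 and 37.8) and Epha3 (10.3, 12.9 and 7.5) the lowest, -0.86 and -0.78. Myc stood at 113.9, 313.2 and 351.4, Snai2 at 510.7, 542.5 and 353.6, Id3 at 3035, 4086 and 4830, and Lgmn at 280.9, 208.0 and 247.5. Gata3 (6.2, 5.7 and 8.4), Dtx1 (9.1, 8.9 and 7.8), Ephb4 (27.5, 38.5 and 28.0) and both probes of Bcl2 (5.5, 7.6 and 6.1, and 24.9, 19.6 and 27.7) also stayed within 2-fold. Hey2 (2.0, 3.2 and 3.4) and Cd44 (3.8, 9.3 and 5.0) were below the brightness limit, and Heyl had a value, 2.5, on the OP9-GFP array alone. The median of the targets was 0.01, at percentile 57.8 of random lists, and its sign turned under quantile and lowess scaling. Among 24 genes that process Notch or carry its signal none reached 2-fold, with a median of -0.05, and Psenen of the gamma-secretase complex (896.9, 753.6 and 1360.2) and Mib1, a ubiquitin ligase for Notch ligands (6.7, 14.7 and 9.1), marked the ends of their range.

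Of 35 cell adhesion molecules, 4 were at least 2-fold higher on the OP9-DL array than on the OP9-GFP array, 3 were lower and 28 lay between. Alcam, an immunoglobulin-type adhesion molecule, stood at 13.9, 5.1 and 58.4 on the OP9, OP9-GFP and OP9-DL arrays, and Cdh2, N-cadherin, was 5.72-fold higher (29.4, 20.7 and 118.5). Beside Cd9, Cdh11, another cadherin, was lower (8.6, 11.8 and 4.9). The median of the group was 0.08, at percentile 91.3 of random lists. None of 11 integrin genes reached 2-fold, and Itgb5 (483.2, 307.2 and 436.4) and Itga8 (21.9, 23.6 and 15.8) lay at the ends of their range. Their median was -0.24, at percentile 6.68.

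Genes for secreted stromal products had lower medians on the OP9-DL array than on the OP9-GFP array. Among 23 chemokine and inflammatory genes, 9 were at least 2-fold lower than on the OP9-GFP array and 1 was higher, with a median log2 difference of -0.36. Il6, an inflammatory cytokine, was 12.8-fold lower (88.0, 174.7 and 13.7) and Il1rn, the interleukin-1 receptor antagonist, 12.2-fold lower (85.6, 166.0 and 13.6), while Ccl5 was 2.28-fold higher. Of 24 stromal factors for blood and mast cells, which include Il6, 3 were lower and 1 higher, with a median of -0.34. Tslp was lower (3.8, 16.9 and 6.0), Igf1 was 5.41-fold higher (10.6, 19.7 and 106.5), and Kitl, the mast cell growth factor SCF, had 7.0, 6.4 and 10.3. Of 42 matrix genes 5 were lower and 2 higher, with a median of -0.21. Col3a1, a fibrillar collagen, was 4.78-fold lower (660.5, 936.4 and 195.9) and Thbs1 3.42-fold lower (216.6, 590.6 and 172.5). Efemp1 was 3.78-fold higher (1638.5, 413.6 and 1564.4) and Lama4 2.38-fold higher (17.5, 8.8 and 20.9). For Tslp, Thbs1 and Efemp1 it was the OP9-GFP array that stood apart. Of the 9 lower chemokine and inflammatory genes, 5 were at least 2-fold lower on the OP9-DL array than on both others. The other 4 were at least 2-fold higher on the OP9-GFP array than on both others. The medians of the chemokine, stromal and matrix lists lay at percentiles 0.03, 0.04 and 0.42 of random lists.

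Cell cycle genes had a lower median and p53 response genes a higher one on the OP9-DL array than on the OP9-GFP array. Of 37 cell cycle genes, 34 lay within 2-fold and 3 were lower, but the median was -0.58, below the middle 95% of random lists. Tyms, the thymidylate synthase, had intensities of 594.4, 1438 and 546.5 on the OP9, OP9-GFP and OP9-DL arrays, and Cdc45, a replication factor, 444.8, 709.7 and 318.6. Of 17 p53 response genes 5 were higher and 1 lower, with a median of 0.55, above that range. Gadd45a, a growth arrest gene, was 4.64-fold higher (114.2, 73.1 and 338.9), while Btg2 was 2.12-fold lower. Cdkn2a was 3.96-fold higher (63.7, 9.8 and 38.8). It encodes the p16 and ARF inhibitors and is counted because the list was fixed beforehand, although p53 does not induce it. Smooth muscle and myofibroblast genes had a median of -0.41, with 1 of 16 higher and 2 lower. Cspg4, the NG2 proteoglycan of pericytes, was 9.89-fold lower (25.1, 90.0 and 9.1). Cnn1, a smooth muscle calponin, was 5.08-fold lower (4.6, 181.2 and 35.7), and Des, desmin, 2.92-fold higher (12.6, 7.4 and 21.6). Against the OP9 array these shifts were not seen. The OP9-DL medians there were 0.24 for cell cycle genes, 0.04 for p53 response genes (percentile 63.25) and 0.73 for smooth muscle genes.

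Interferon-stimulated genes had a median of 0.18, at percentile 99.6, with 4 of 30 higher and 3 lower: Ifi27 was 2.31-fold and Stat2 2.29-fold higher, and Psmb8, an immunoproteasome subunit, was 8.44-fold lower. In all, 7 of the 29 lists lay outside the middle 95% of random lists, 2 above and 5 below. By chance 1.45 would lie outside if the genes within a list varied independently. Genes of one pathway vary together, so the excess cannot be weighed against that number. The other 22 medians ran from -0.32 to 0.22. Among them, adipocyte genes (-0.08) had 1 of 28 higher, Dgat2, and 4 lower, with Cfd 9.27-fold and Adipoq 3.38-fold lower. Of 19 osteoblast and cartilage genes (-0.04), Col2a1 was 2.04-fold higher and Alpl, alkaline phosphatase, 6.71-fold lower. Of 23 unfolded protein and stress genes (-0.02, above 0 under quantile and lowess scaling) 3 were higher and 3 lower, with Trib3 5.26-fold and Ddit3 3.37-fold higher and Hspb1, a small heat shock protein, 46.1-fold lower. Matrix proteases and inhibitors (-0.15) had 3 of 19 lower, among them Ctsk, cathepsin K, by a factor of 3.55 and Plat by 2.92. The medians were -0.06 for TGF-beta and BMP response genes, where Fst was 2.34-fold higher and Tgfbi 5.76-fold lower, and -0.16 for Wnt pathway genes, where Sfrp4 stood at 65.8, 24.2 and 3.8.

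The markers of other cell types had medians near 0 between these arrays. The median of 8 mast cell markers was 0.01 and that of 11 haematopoietic and macrophage markers 0.06, and Tpsab1 and Cd48 were their only members past 2-fold. Of the 8 mast cell markers, Cpa3, a mast cell carboxypeptidase, had 4.9, 8.1 and 6.7. Below the brightness limit, Ptprc, the leukocyte antigen CD45, had 2.1, 2.5 and 2.8, and Kit had a value on the OP9 array alone, 1.6. No endothelial or epithelial marker, no cholesterol synthesis gene, no Hox gene and no ribosomal protein gene reached 2-fold, and the medians of these lists were 0.12, -0.07, -0.09, 0.01 (below 0 under lowess scaling) and 0.19. The medians were -0.04 for glycolysis and hypoxia genes, with Slc2a1 2.29-fold lower, -0.08 for immediate early genes, with Nr4a1 3.32-fold lower, and -0.03 for reference genes, where Tfrc was 2.52-fold lower.

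How far probes of the same gene agree can be read from genes with several probes. Such probes read the same RNA on the same arrays, so they do not show how repeatable a difference between cultures is. Over 129 such genes, the correlation between the probes' log2 differences of OP9-DL against OP9-GFP was 0.04, and of 11 genes with a probe past 2-fold, 6 had the same sign on both probes and 0 had both past 2-fold. Most folds given for OP9-DL against OP9-GFP rest on a single probe, and this limit applies to them. In the comparisons with OP9 the correlation was 0.51 for OP9-DL and 0.51 for OP9-GFP. These correlations are across genes, which are not independent replicates.

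**Figure D2:**
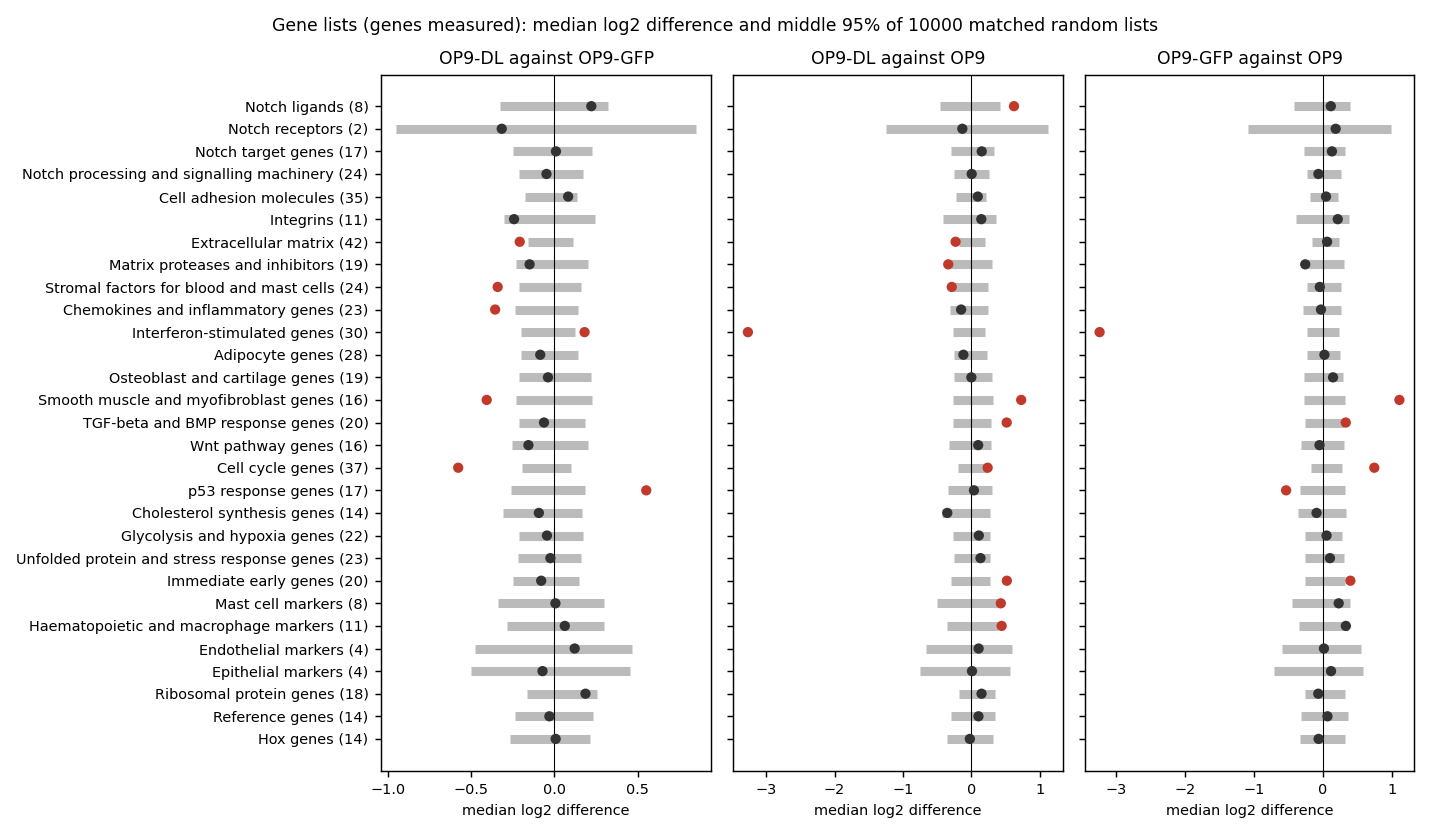
Median log2 difference of each gene list in the 3 comparisons (one panel each, with different horizontal ranges), beside the middle 95% of random lists matched on brightness. Interferon-stimulated genes lie at -3.24 in OP9-GFP against OP9 and at 0.18 in OP9-DL against OP9-GFP, and cell cycle genes at 0.74 and -0.58.

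The second comparison set the cells with GFP alone against the parental cells, which differ without Delta-like 1. Interferon-stimulated genes were lower on the OP9-GFP array: 26 of 30 were at least 2-fold lower and 0 higher, with a median log2 difference of -3.24, below the middle 95% of random lists. Ifi44 had intensities of 324.4 on the OP9 array, 12.1 on the OP9-GFP array and 2.5 on the OP9-DL array. Ifit3, which binds viral RNA complexes, had 269.5, 5.4 and 10.6, Oas2, an oligoadenylate synthetase, 295.7, 7.9 and 12.6, and Gbp4, a guanylate-binding protein, 88.6, 5.0 and 4.4 by one probe and 37.4, 4.4 and 2.7 by the other. Across all probes, 757 were at least 2-fold higher and 1051 lower, 11.6% of those compared.

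Smooth muscle and myofibroblast genes had a higher median on the OP9-GFP array than on the OP9 array. Of 16 such genes 9 were at least 2-fold higher and 1 lower, and 11 lay above 0. Their median was 1.11, and 0.50 without the limit on dim probes. Tagln, transgelin, had intensities of 362.3, 7468 and 4079 on the OP9, OP9-GFP and OP9-DL arrays, and Actg2, a smooth muscle actin, 164.9, 2926 and 1943. Ccn2, connective tissue growth factor, had 256.2, 3524 and 2884, and Edn1, endothelin-1, 2.3, 112.2 and 71.7. Of 20 TGF-beta and BMP response genes 6 were higher and 2 lower (median 0.33, percentile 98.5), and of 20 immediate early genes 7 were higher and 0 lower (median 0.40, percentile 99.4), with Maff 4.64-fold higher. Hsd11b1, which activates glucocorticoids, stood at 19.5, 210.4 and 1020, and Aif1l at 3.8, 82.7 and 115.3. On the OP9 array Ltc4s, leukotriene C4 synthase, had 408.3 against 20.7 and 10.4, and Mgl1, named as on the array, 71.9 against 3.0 and 2.6.

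Cell cycle genes were also higher on the OP9-GFP array, 10 of 37 by 2-fold or more and 0 lower, with a median of 0.74, above the middle 95% of random lists. Rrm2, a ribonucleotide reductase subunit, was 2.30-fold higher and Tyms 2.42-fold higher. Of 17 p53 response genes 5 were lower and 1 higher, with a median of -0.54 at percentile 0.19, and Cdkn2a was 6.50-fold lower. Genes that set OP9-GFP apart from both other lines included Ptn, the growth factor pleiotrophin (16.8, 261.9 and 13.7), Cfd, adipsin (17.0, 399.5 and 43.1), Serping1, the C1 inhibitor (4.3, 47.0 and 5.7), and Hspb1 (253.4, 1332 and 28.9). Rassf6 was 8.72-fold higher than on the OP9 array, and Ttll11 stood at 3.2, 88.8 and 9.3. On the low side, Renbp, the renin-binding protein, stood at 101.3, 8.4 and 159.6, Sncg, gamma-synuclein, at 984.2, 209.0 and 1008, Tmem45a at 91.4, 17.2 and 76.0, and Gjb5, a connexin, at 106.4, 14.1 and 56.6. Cideb stood at 23.0, 3.5 and 14.1 and Akr1c13 at 35.0, 6.9 and 147.2, the last uncertain because of its near-identical neighbours. The other 23 lists lay inside the middle 95% of random lists, with medians from -0.26 to 0.33. Among these were the Notch targets (0.13, with 3 of 17 higher), Notch ligands (0.11), matrix genes (0.06, with 9 of 42 higher and 5 lower) and adipocyte genes (0.02, with Cfd 23.5-fold and Adipoq 17.1-fold higher). Mast cell markers had a median of 0.23 and haematopoietic markers one of 0.33, at percentiles 87.9 and 96.3.

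The last comparison set the cells with Delta-like 1 against the parental cells. Here 26 of 30 interferon-stimulated genes were again at least 2-fold lower and 0 higher, with a median of -3.27, and Psmb8 stood at 1449 on the OP9 array, 112.2 on the OP9-GFP array and 13.3 on the OP9-DL array. Smooth muscle genes (0.73, with 5 of 16 higher and 2 lower), TGF-beta and BMP response genes (0.52, with 6 of 20 higher and 2 lower) and immediate early genes (0.52, with 6 of 20 higher and 2 lower) had medians above the middle 95% of random lists. Id2, an inhibitor of helix-loop-helix factors, was 3.52-fold higher and Tgfbi 17.6-fold lower. Notch ligands, a list that holds Dll1 itself, had a median of 0.62 at percentile 99.8, with 3 of 8 higher, Dll1, Dlk1 and Mfap5. With the brightness limit at the 50th percentile only Dll1, Dlk2 and Mfap5 stayed, and the median of 1.98 is the value of Mfap5 alone. Cell cycle genes had a median of 0.24 at percentile 97.8, at the edge of the range and inside it under lowess scaling. Of the Notch targets 4 of 17 were higher, Hes1 2.01-fold, Dtx4 2.28-fold, Myc 3.08-fold and Efnb2 2.52-fold, and 3 of these were also 2-fold higher on the OP9-GFP array than on the OP9 array. Over all probes 672 were higher and 1077 lower, 11.2%.

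Stromal and matrix lists had medians below 0 in this comparison too. Of 24 stromal factors 7 were lower and 1 higher (median -0.29, percentile 1.75), with Igf1 higher by 3.33 on the log2 scale and Il6 6.42-fold lower. Chemokine and inflammatory genes had a median of -0.15 inside the range (percentile 19.2), with 9 of 23 lower and 4 higher. Matrix genes had a median of -0.23 (percentile 0.67) with 6 of 42 lower and 5 higher, and matrix proteases and inhibitors one of -0.34 (percentile 1.36, at the edge of the range under lowess scaling) with 4 of 19 lower, Ctsk by a factor of 6.52. Mast cell markers had a median of 0.43 at percentile 98.1, and haematopoietic and macrophage markers one of 0.44 at percentile 98.7, with 2 of 8 and 1 of 11 members higher. Thus 11 of 29 lists lay outside the middle 95%, 7 above and 4 below. Of the adhesion molecules 5 of 35 were higher and 1 lower, with Alcam 4.20-fold and Cdh2 4.03-fold higher and a median of 0.09 inside the range.

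Both lines that carry GFP differed from the parental array largely in the same direction. Across probes, the log2 differences of OP9-DL against OP9 and of OP9-GFP against OP9 had a Pearson correlation of 0.72 and a Spearman correlation of 0.70. Both use the OP9 array, and shuffling each probe's values among the arrays gave a correlation of 0.50, with a covariance of 0.24 against the 0.39 observed. In both comparisons 343 probes were higher and 620 lower, and 27 went opposite ways, where shuffling gave 236 and 298 on average and independent lists of these sizes would share 32.6 and 72.6. Sharing an array builds in some overlap. Shuffling only exchanges the arrays, so the shuffled covariance and overlaps are close to averages of the observed ones over the lines. They do not show how much of the overlap comes with the shared array, since shuffled values still hold real differences between lines.

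**Figure D3:**
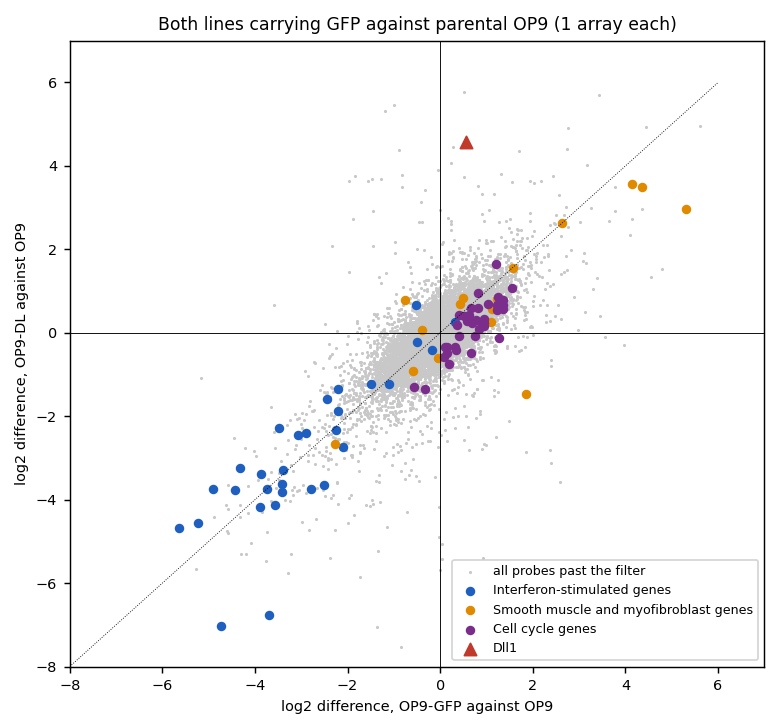
Log2 difference of OP9-DL against OP9 set against that of OP9-GFP against OP9, 1 point per probe (15581 probes), with the dotted line marking equality. The correlation across probes is 0.72 (0.50 after shuffling), and both axes share the OP9 array.

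Taken line by line, OP9 stood apart from both others at 963 probes (620 higher and 343 lower), OP9-DL at 378 (151 and 227) and OP9-GFP at 260 (123 and 137). Shuffling each probe's values among the arrays only changes which line stands apart and keeps the total of such cases. The shuffled averages of 534, 531 and 536 are therefore close to the mean of the observed counts and are no outside reference. OP9 lay above that mean and both lines with GFP below it, so the cases fell most often on OP9. Dll1, Tpsab1 and Cd9 were among the 378 probes of OP9-DL, and Ifi44, Oas2, Tagln and Ccn2 among the 963 of OP9. The correlation of log2 intensities across probes was 0.974 between the OP9-DL and OP9-GFP arrays, 0.958 between OP9-GFP and OP9 and 0.951 between OP9-DL and OP9.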

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

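The tests on chromosome 12 were chosen after its shift had been seen, as were the reading of the growth state result and the use of blank values for Kit described here. In the first of these, the criterion written beforehand for growth state as the cause was met, and it is called open here only because of a further value looked at afterwards. In the second, Kit had no value on the OP9-GFP and OP9-DL arrays, so its blanks were set to each array's lowest value.

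Some probes with no value on another array, and so outside the comparisons, were bright on the OP9-DL array. Gpr63 had 22 on the OP9-DL array, 1.2 on the OP9 array and no value on the OP9-GFP array. 3830403N18Rik had 147.2 on the OP9-DL array, 1.3 on the OP9-GFP array and no value on the OP9 array. A pair of probes without a gene name had 24.4 and 78.2 on the OP9-DL array, against 2.0 and 2.8 on the OP9 array and no value on the OP9-GFP array.

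Interferon-stimulated genes were higher on the parental array than on both arrays of cells with GFP. Scaling by brightness is argued against by the random lists matched on brightness, whose median was 0.01 in OP9-GFP against OP9. With the brightness trend removed, the median of the list in that comparison was -3.27. A trend fitted over all probes could hardly have changed it. Blood cells as a whole in the parental culture are argued against too. The median of 11 blood cell markers on the OP9 array minus the mean of the others was -0.29, and 0 were at least 2-fold higher there than on both others. These markers cover several kinds of blood cells, and Cd14 was highest on the OP9 array (55.6, 34.0 and 23.0). The median therefore cannot exclude a single kind of blood cell. Cell cycle genes on the OP9 array minus the mean of the others were lower, -0.53, which meets the size set beforehand for growth state as a cause. The OP9-DL array differed from the OP9-GFP array by -0.58 in cell cycle genes and by 0.18 in interferon genes. That 0.18, at percentile 99.6 of random lists, goes in the same direction as on the OP9 array but is far smaller. With 1 culture per line, growth state and line cannot be told apart. A difference between the lines or an infection or activation of the parental culture may equally lie behind the interferon difference, untested.

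Tpsab1 and Cd48, markers of mast cells and of blood cells, were far higher on the OP9-DL array than on both others. Mast cells in that culture are argued against: the other 7 mast cell markers had a median of 0.10 on the OP9-DL array minus the mean of the others. Among these 7, Cpa3, abundant in mast cells, stood at 4.9, 8.1 and 6.7 on the OP9, OP9-GFP and OP9-DL arrays. Other blood cells are argued against by a median of 0.063 over 10 other markers, with Ptprc at 2.1, 2.5 and 2.8. Against OP9 alone both marker lists lay above the middle 95% of random lists on the OP9-DL array (0.43 and 0.44), which goes with such cells, while against OP9-GFP their medians were 0.01 and 0.06. Expression of Tpsab1 and Cd48 by the OP9-DL cells themselves, or a probe that reads another transcript, may explain the values and was not tested.

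Genes of single chromosomes shifted together: in OP9-DL against OP9-GFP the medians of 11 of 20 chromosomes lay outside the middle 95% of random gene sets, where 1 would by chance for independent genes, and that of chromosome 12 was highest at 0.27 over 365 genes. Scaling by brightness is argued against by the random sets, which were matched on brightness. With the brightness trend removed the median of chromosome 12 was 0.28. A trend fitted over all probes could hardly have changed it, so this value adds nothing. Among its dimmer and among its brighter genes, at least 68.7% lay above the median of all genes, but this largely restates the shift for which the chromosome was picked and decides nothing on its own. A different copy number of chromosome 12 in the lines stays open: the lowest median of 3 successive parts was 0.25, but the chromosome had been picked for its shift, so this lends that hypothesis no support. No DNA was measured.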

How the results depend on the processing

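The count of probes with a symbol only was added after the data were seen; the other alternatives were planned. Under quantile, median and lowess scaling, the added constant, blanks at the lowest value and probes with a symbol only, each of the 12 counts stayed within 1.5 times its main value, and no scaling moved the median of all probes by more than 0.031 on the log2 scale. All 21 recomputed correlations stayed within 0.1. Of 693 list medians 691 stayed within 1.5-fold of their main value. That limit is 0.585 on the log2 scale and exceeds most of the medians themselves. A small median could vanish or turn in sign and still be counted as unmoved, so this count says little on their stability. The others were smooth muscle genes in OP9-GFP against OP9 (0.50 with no limit on dim probes) and Notch ligands in OP9-DL against OP9. The ligands had 1.98 with the limit at the 50th percentile, which is the value of Mfap5 alone. In both lists more or fewer dim genes entered. Of 1800 differences of named genes 1771 stayed within 1.5-fold and 27 moved, all under the added constant, which shrinks differences of dim probes (Akip1 in OP9-DL against OP9, -5.86). With only the brightest probe per gene, Pdgfrl reversed, to -0.72 in OP9-DL against OP9-GFP and -0.21 in OP9-DL against OP9, because its probes disagree.

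Counts moved with the limit on dim probes and the threshold, as their construction implies. With no limit, 688 probes were higher and 655 lower in OP9-DL against OP9-GFP, 1051 higher in OP9-DL against OP9, 193 and 251 set OP9-GFP apart (higher, lower) and 247 set OP9-DL apart as higher. With the limit at the 50th percentile, these were 214 and 243, 434, 64 (OP9-GFP higher), and 73 and 139 (OP9-DL higher, lower). At 1.5-fold, higher and lower counts were 1206 and 1313 (OP9-DL against OP9-GFP), 2058 and 2435 (OP9-DL against OP9), 2173 and 2401 (OP9-GFP against OP9), and those of lines apart 1554 and 1150 (OP9), 525 and 501 (OP9-GFP) and 472 and 593 (OP9-DL). At 3-fold they were 110 and 165, 216 and 440, 189 and 368, and 234 and 81, 37 and 29, and 60 and 100, in the same order.

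No paired analysis was possible because each line has 1 array and the labels give no replicate numbers, and leaving out an array leaves a line with none. Signal limits the dimmest probes, where blanks begin near an intensity of 1, and the brightest, where probes share the highest value.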

Other observations

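Whole chromosomes were compared only after their shifts had been noticed, and the genes and windows named here were chosen after their values were seen. In OP9-DL against OP9-GFP, the medians of the chromosomes ran from -0.24 to 0.27, with chromosomes 13 and 18 at the low end and chromosome 12 at the high end. In OP9-DL against OP9, 16 of 20 chromosomes lay outside the middle 95% of random gene sets, and in OP9-GFP against OP9 14 did. Among windows of 15 neighbouring genes, the highest in OP9-DL against OP9 lay on chromosome 10 between Llph and Mettl1, with a median of 1.05 and all 15 genes above 0, beyond the highest of 0.80 in 100 shuffles of gene order. The lowest in OP9-GFP against OP9 lay on chromosome 5 between Dtx1 and Acad10, with a median of -1.30 against a lowest of -0.99 in the shuffles. The same window was the lowest in OP9-DL against OP9, at -0.89, which lay inside the range of the shuffles. That stretch includes the interferon-stimulated gene Oas2, and how far such genes carry its median was not tested. In OP9-DL against OP9-GFP, the lowest window lay on chromosome 11 between Srebf1 and Map2k3os (-0.75, against a lowest of -0.70 in the shuffles) and the highest on chromosome 10 between Tspan31 and Stac3 (0.62, against a highest of 0.59).

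Further single genes differed between the lines. Tmem176b stood at 37.2, 9.5 and 465.9 on the OP9, OP9-GFP and OP9-DL arrays, beside its neighbour Tmem176a at 23.4, 6.5 and 317.7. Spp1, osteopontin, stood at 26149, 5611 and 6878, and Rb1, the retinoblastoma protein, at 1404.6, 279.3 and 992.9. Selp, P-selectin, an adhesion molecule for leukocytes, stood at 9.9, 20.4 and 75.8, while Vcam1, which binds integrins of blood cells, stood at 339.6, 242.6 and 350.3. Cxcl12, a chemokine that retains blood cells in bone marrow, stood at 3720, 4411 and 1997.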
